A study of Mus musculus with 72 samples.

How the data were processed

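The series holds 72 messenger RNA libraries of mouse macrophages in 4 experiments, which the submitters' labels describe as stranded TruSeq libraries from 500 ng of RNA. The groups were formed from the labels by experiment, genotype and treatment, which gave 24 groups of 3 libraries. The control marrow-derived cells carry wt in their titles and Setd1bHet as their genotype label, and are called control here. The labels speak of 3 biological replicates without saying whether these were separate animals or separate cultures, so the p-values measure the spread between libraries whose separateness is not fully stated. No label gives a sequencing batch or date.

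Per the labels and values, the authors' deposited tables hold TPM, transcript abundances scaled to a fixed total per library and summed per gene. No header names the unit of the IFNB1 table. Its values, given to 1 decimal, were checked against the 6 h experiment: over 8940 genes the wild-type LPS means had a Spearman correlation of 0.856 and a median ratio of 1.22. The deposited tables also hold the authors' log2 fold changes for Dex with LPS over LPS and for IFNB1 with LPS over LPS. They hold p-values and adjusted p-values of these. Other columns are the authors' mean normalized counts and classes of the response in RAW264.7 cells. The submitters' processing notes name Salmon 0.10.2, R 3.6.0, DESeq2 and the assembly GRCm38.p6, also called mm10, and the release of the annotation is not given in the sources used here. The tables for Dex list 8983 genes (RAW264.7) and 9179 genes (marrow-derived), and that for IFNB1 lists 18254, so that the listed values of a library sum to less than 1e+06 TPM. The number of reads per library is unknown, and no counting interval can be given. The tables were normalized separately, and every test was made within a table. Coordinates come from GENCODE vM21 on GRCm38, matched by gene identifier, and 8967 of 8983, 9170 of 9179 and 18254 of 18254 listed genes had a matching entry.

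Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9). Values were log2(TPM + 1), the model had 1 mean per group, and eBayes was run with a trend. Genes with at least 1 TPM in at least 3 libraries of the experiment were tested, which left 9159 genes in the marrow-derived cells, 8964 and 8981 in the 16 h and 6 h RAW264.7 experiments and 10923 in the IFNB1 experiment. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. The comparisons between 16 h and 6 h came from 1 joint fit of both experiments. The 33 comparisons, the 8 sets chosen in other libraries, the 29 gene lists and the alternatives were fixed before the data were examined, and 1 comparison, the deletion effect under LPS at 16 h minus 6 h, was added afterwards. Lists and sets were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison or over the 8 sets, and again with an estimated correlation. List calls hold with an estimated correlation unless a second adjusted p is printed. A count adjusted over the list alone is the number of its genes with an adjusted p under 0.05 when only the list's genes are corrected together. Effects that share a control group correlate by construction, and 100 simulations of noise gave the size of that correlation.

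The text names genes by a rule fixed before the data were examined. In each comparison it may name the 8 highest and 8 lowest log2 changes among called genes with at least 5 TPM in the higher group and no overlap between the groups. It may also name up to 4 called members of each list with the largest changes and the 2 most expressed members that were not called. A further 22 genes, among them Setd1a, Setd1b, Nr3c1, Tsc22d3, Il1b and Ifit1, could be named in any comparison.

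The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling of the TPM values, a replicate block, a fit of the compared groups alone, another fold minimum for the sets, an estimated correlation, and leaving out each library in turn. A count within 1.5 times the main count was taken as the same, and a value past the threshold under neither setting was taken as unchanged whatever its sign. Tests on counts were not run because the tables hold TPM. Samples were regrouped in all 10 splits of 3 against 3 libraries, or in 100 of 200 splits for a difference of effects, drawn with seed 1. The method was tested on simulated data: in the marrow-derived LPS comparison it recovered 89.55% of genes changed by 0.5 on the log2 scale and 98.51% of those changed by 1, and for the difference of Dex responses at 6 h 56.72% and 91.04%. Of the simulated calls 4.09% to 7.14% were false, by comparison. No pair of libraries was identical, and the lowest Pearson correlation between replicates was 0.984. All 72 sample columns were used. The authors' fold changes and p-values were compared with the limma results and used in no test.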

Results

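Messenger RNA was sequenced from mouse macrophages in 72 libraries that fall into 24 groups of 3. Bone marrow-derived macrophages, which are primary cells differentiated for 7 days with growth factors from L929 cells, were compared between control cells and cells labelled Setd1bKO. RAW264.7 cells, a macrophage line from BALB/c mice, were compared between wild-type cells and cells with a heterozygous deletion in Setd1a, labelled Setd1aDel. Setd1a and Setd1b are the catalytic subunits of COMPASS complexes, which methylate histone H3 at lysine 4. Cells received vehicle, bacterial lipopolysaccharide (LPS, 100 ng/ml for 6 h), or LPS with the synthetic glucocorticoid dexamethasone (Dex, 1 uM), which acts through the glucocorticoid receptor Nr3c1. Dex or its ethanol vehicle was given for 16 h in the marrow-derived cells and in 1 RAW264.7 experiment, and for 6 h in another, which also held Dex alone. A further RAW264.7 experiment compared LPS with LPS plus 10 ng/ml interferon beta (IFNB1) for 6 h. The series describes the marrow-derived cells as a study of Setd1b as a nuclear partner of the glucocorticoid receptor, and the RAW264.7 cells as a study of expression that depends on Setd1a. Values were TPM, so the number of reads behind a library is unknown. The listed genes summed to 837032 to 909974 TPM per library in the marrow-derived cells. In RAW264.7 cells they summed to 894029 to 912839 with 16 h of Dex, 902114 to 911851 with 6 h and 894929 to 905329 with IFNB1. Changes below are on the log2 scale with their standard error, TPM values are means with their SD, and each group has n = 3.

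In control marrow-derived macrophages LPS raised inflammatory genes and lowered genes of DNA replication. Il1b (9.53 ± 0.065), which encodes interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), went from 15.5 ± 1.05 to 12201 ± 96.2 TPM. The neutrophil attractants Cxcl3 (9.55 ± 0.084) and Cxcl2 (9.01 ± 0.12), the cytokines Il6 (9.37 ± 0.079), Il12b (9.02 ± 0.10) and Tnf (7.89 ± 0.084), the prostaglandin synthase Ptgs2 (8.95 ± 0.13) and the nitric oxide synthase Nos2 (7.41 ± 0.077) rose with it. Interferon beta itself, Ifnb1, was listed at 0 TPM in the vehicle libraries and had 8.84 ± 0.972 TPM with LPS. Of LPS-induced cytokines and chemokines, 30 of 30 rose (30 adjusted over the list alone, median 6.94, adjusted p = 1.91e-30). Interferon-stimulated genes moved the same way, as 57 of 57 rose (57 adjusted over the list alone, median 4.25, adjusted p = 3.67e-44), among them Cxcl10 (9.25 ± 0.11), Mx1 (7.79 ± 0.24) and Ifit1 (7.64 ± 0.059). Of feedback inhibitors of NF-kB, MAPK and JAK signalling, 18 of 23 rose and 5 fell (23 adjusted over the list alone, median 2.55, adjusted p = 5.18e-12), with Socs3 (7.34 ± 0.13) the furthest. Antigen presentation genes followed, of which 18 of 21 rose and 2 fell (20 adjusted over the list alone, median 1.65, adjusted p = 6.9e-11), with the costimulatory receptor Cd40 (8.79 ± 0.10) among them. Genes of DNA replication and mitosis went down: 33 of 35 fell and 2 rose (35 adjusted over the list alone, median -2.10, adjusted p = 2.1e-05, adjusted p = 0.104 with an estimated correlation), including the centromere histone Cenpa (-4.30 ± 0.36), the ribonucleotide reductase Rrm2 (-3.90 ± 0.10) and the thymidine kinase Tk1 (-3.47 ± 0.094). Other genes that fell were Cd300lb (-6.41 ± 0.14), Cxcr4 (-5.12 ± 0.10), Pparg (-3.86 ± 0.077) and the glucocorticoid target Tsc22d3 (-5.03 ± 0.15). The receptor gene itself rose, Nr3c1 (1.31 ± 0.24), while its target Fkbp5 (-0.12 ± 0.086, adjusted p = 0.198) was not called but was called with 0.31 after median-of-ratios scaling and with -0.20 without control vehicle replicate 1. In all 1887 of 9159 tested genes rose and 5925 fell by limma, and the 3 LPS values lay apart from the 3 vehicle values for 7996 genes (87.3%, against 10% by chance). The median of all tested genes was -0.49, which median-of-ratios scaling moved by 0.49. Relative to the typical gene every value in this paragraph is therefore higher by that amount, and after scaling 3561 genes rose and 3566 fell.

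Dex on top of LPS raised known glucocorticoid targets in control marrow-derived macrophages and lowered part of the LPS response. Tsc22d3 (4.95 ± 0.15), which encodes the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), went from 2.02 ± 0.697 to 90.9 ± 12.3 TPM. Fkbp5 (3.21 ± 0.086) went from 4.06 ± 0.334 to 45.9 ± 1.83 TPM, and the phosphatase Dusp1 (2.84 ± 0.055), the clock gene Per1 (3.44 ± 0.19), the transcription factor Klf9 (2.38 ± 0.13), the metallothioneins Mt1 (3.65 ± 0.066) and Mt2 (4.28 ± 0.11) and the lipocalin Lcn2 (3.15 ± 0.10) rose as well. Of glucocorticoid-induced genes, 17 of 26 rose and 4 fell (21 adjusted over the list alone, median 0.60, adjusted p = 0.000668). The chemokines Ccl22 (-3.69 ± 0.20), Ccl7 (-3.24 ± 0.13) and Ccl2 (-1.77 ± 0.075), the cholesterol hydroxylase Ch25h (-3.68 ± 0.12) and the activin subunit Inhba (-3.07 ± 0.17) fell, as did Nos2 (-2.56 ± 0.077), Il12b (-1.68 ± 0.10), Il1b (-1.51 ± 0.065) and Il6 (-1.18 ± 0.079). Among LPS-induced cytokines and chemokines, 20 of 30 fell and 5 rose (25 adjusted over the list alone, median -1.30, adjusted p = 3.97e-12). Tumour necrosis factor was not called, Tnf (0.04 ± 0.084, adjusted p = 0.704). Of interferon-stimulated genes, 52 of 57 fell and 0 rose (52 adjusted over the list alone, median -0.63, adjusted p = 2.27e-30), with Cxcl10 (-1.88 ± 0.11) and Ifit1 (-0.98 ± 0.059) as examples. Antigen presentation genes were lower with Dex, since 18 of 21 fell and 2 rose (20 adjusted over the list alone, median -0.48, adjusted p = 1.41e-11), among them the invariant chain Cd74 (-2.07 ± 0.089). Of osteoclast markers, 9 of 11 fell and 1 rose (10 adjusted over the list alone, median -0.66, adjusted p = 6.66e-07). By limma 4100 of 9159 tested genes rose and 1389 fell, and 6152 genes did not overlap between the groups (67.17%, against 10% by chance). The median of all genes was 0.18, which scaling moved by -0.19. After scaling 1883 genes rose and 2455 fell.

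The libraries labelled Setd1bKO were compared with control to measure expression that depends on Setd1b. Setd1b (ENSMUSG00000038384, chromosome 5, 123142193 to 123168629) had 4.54 ± 0.681 TPM in control and 10.1 ± 0.359 TPM in the libraries labelled Setd1bKO in vehicle, a change of 1.00 ± 0.21 (adjusted p = 0.00235). With LPS its change was 0.20 ± 0.21 (adjusted p = 0.49), and with Dex and LPS it was 0.13 ± 0.21 (adjusted p = 0.68). The labels do not say which exons were removed, and a gene-level TPM sums over all of them. In vehicle the libraries labelled Setd1bKO had lower macrophage surface and cell cycle genes. The scavenger protein Cd5l (-3.24 ± 0.075) went from 163 ± 3.04 to 16.4 ± 0.793 TPM and the pore-forming Mpeg1 (-3.04 ± 0.052) from 1102 ± 32.2 to 133 ± 2.68 TPM. The Fc receptor Fcgr1 (-2.50 ± 0.12), the NADPH oxidase subunit Cybb (-2.26 ± 0.11), the scavenger receptor Stab1 (-2.26 ± 0.19) and the macrophage marker Adgre1 (-1.36 ± 0.043) were lower too. Of macrophage identity genes, 15 of 27 were lower and 4 were higher (21 adjusted over the list alone, median -0.58, adjusted p = 7.75e-07). Of DNA replication and mitosis genes, 32 of 35 were lower and 0 were higher (33 adjusted over the list alone, median -0.76, adjusted p = 7.18e-24), including Tk1 (-1.69 ± 0.094), Rrm2 (-1.52 ± 0.10), Top2a (-1.50 ± 0.067) and Mki67 (-1.23 ± 0.10). Of interferon-stimulated genes, 38 of 57 were lower and 0 were higher (42 adjusted over the list alone, median -0.29, adjusted p = 7.4e-11, adjusted p = 0.26 with an estimated correlation). The receptor gene was lower, Nr3c1 (-0.71 ± 0.24, adjusted p = 0.0438), a call that ended when only the compared groups were fitted, or without control replicate 1 (-0.68) or 2 (-0.48) or without replicate 1 (-0.74), 2 (-0.75) or 3 (-0.65) labelled Setd1bKO (adjusted p = 0.0742 to 0.206). Among higher genes, the chemokine Ccl8 (2.47 ± 0.12) went from 4.69 ± 1.03 to 30.1 ± 1.64 TPM, and the glucose transporter Slc2a3 (1.65 ± 0.15) was higher as well. In all, 906 of 9159 tested genes were higher and 1413 were lower by limma, 19 and 158 of them by at least 2-fold (279 together, against 177, with a pseudocount of 0.1). With scaling 1017 were higher and 1317 lower.

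Under LPS the libraries labelled Setd1bKO had less of the Fc receptor Fcgr1 (-4.30 ± 0.12), which went from 92.9 ± 3.09 to 3.78 ± 0.610 TPM, and more of the growth factor Csf2 (3.50 ± 0.12), from 32.7 ± 4.38 to 377 ± 8.97 TPM. The interleukin Il23a (2.57 ± 0.082), the vasodilator Adm (2.87 ± 0.16), Ccl2 (1.46 ± 0.075) and Tnf (0.89 ± 0.084) were higher, and Il1b (0.52 ± 0.065) with them. Tgfbi (-3.35 ± 0.074), Cd5l (-3.22 ± 0.075), Inhba (-3.12 ± 0.17) and the interleukin 1 antagonist Il1rn (-2.43 ± 0.078) were lower. Of interferon-stimulated genes, 49 of 57 were lower and 1 was higher (50 adjusted over the list alone, median -0.65, adjusted p = 1.13e-27, adjusted p = 0.0745 with an estimated correlation). Ifit3 (-2.52 ± 0.083) went from 686 ± 27.5 to 119 ± 9.60 TPM, and Oasl1 (-1.84 ± 0.084), Ifit1 (-1.01 ± 0.059) and Cxcl10 (-0.83 ± 0.11) were lower as well. Of macrophage identity genes, 17 of 27 were lower and 4 were higher (23 adjusted over the list alone, median -0.52, adjusted p = 6.76e-13). Oxidative stress genes went the other way, as 15 of 23 were higher and 4 were lower (19 adjusted over the list alone, median 0.31, adjusted p = 0.00562, adjusted p = 0.181 with an estimated correlation). Il6 (-0.52 ± 0.079) was lower. By limma 2656 of 9159 tested genes were higher and 1140 were lower, with 4780 genes not overlapping (52.19%, against 10% by chance). The median of all genes was 0.10, which scaling moved by -0.10, and after scaling 1452 genes were higher and 1825 lower.

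With Dex and LPS the same comparison gave Adm (3.05 ± 0.16), Mmp3 (2.67 ± 0.083), Il23a (2.55 ± 0.082) and Il1b (1.16 ± 0.065) as higher. Ccl2 (2.45 ± 0.075) went from 521 ± 33.2 to 2855 ± 145 TPM. The membrane protein Ms4a4a (-3.23 ± 0.11), Cd5l (-3.09 ± 0.075) and Fcgr1 (-2.67 ± 0.12) were lower, and among glucocorticoid targets Tsc22d3 (-0.58 ± 0.15, adjusted p = 0.00843) and Fkbp5 (-0.36 ± 0.086, adjusted p = 0.00447) were lower. Of glucocorticoid-induced genes, 11 of 26 were lower and 6 were higher (18 adjusted over the list alone, median -0.14, adjusted p = 0.006, adjusted p = 0.0638 with an estimated correlation). Of interferon-stimulated genes, 42 of 57 were lower and 0 were higher (46 adjusted over the list alone, median -0.43, adjusted p = 7.56e-23, adjusted p = 0.066 with an estimated correlation). In total 2149 of 9159 tested genes were higher and 1054 were lower, and after scaling 1178 were higher and 1511 lower.

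Whether the responses themselves differed between the libraries labelled Setd1bKO and control was tested as a difference of log2 changes. The LPS response differed for 2000 genes, 1503 in the positive direction. Csf2 (2.92 ± 0.17), Il23a (2.54 ± 0.12), Ccl2 (2.33 ± 0.11) and Adm (2.82 ± 0.23) had positive differences, and Mki67 (2.29 ± 0.15) did as well. Lipg (-2.87 ± 0.12), Fcgr1 (-1.80 ± 0.16) and the interferon-stimulated Slfn4 (-1.85 ± 0.24) had negative differences. Among DNA replication and mitosis genes, 26 of 35 had positive and 0 negative differences (27 adjusted over the list alone, median 0.83, adjusted p = 3.17e-14). The median of all genes was 0.11, which scaling moved by -0.13, and with scaling 782 genes had positive and 937 negative differences. Dex under LPS in the libraries labelled Setd1bKO raised Tsc22d3 (4.31 ± 0.15) and Fkbp5 (3.01 ± 0.086) and lowered Il1b (-0.87 ± 0.065) and Nos2 (-1.98 ± 0.077). In all 3591 of 9159 tested genes rose and 1234 fell. The median of all genes was 0.15, which scaling moved by -0.16, and with scaling 1403 rose and 2179 fell. This response differed from that of control for 569 genes, 246 positive and 323 negative. Positive differences included Ch25h (1.95 ± 0.17), Ccl7 (1.71 ± 0.18), Fcgr1 (1.63 ± 0.16), Ccl2 (0.99 ± 0.11) and Il1b (0.64 ± 0.092). Negative differences included Ms4a4a (-2.33 ± 0.16), Ifnb1 (-2.04 ± 0.32), Csf2 (-1.44 ± 0.17), Rhob (-1.41 ± 0.065), Tns1 (-0.97 ± 0.18) and Klf9 (-0.91 ± 0.18), while those of Tsc22d3 (-0.63 ± 0.22, adjusted p = 0.108) and Fkbp5 (-0.20 ± 0.12, adjusted p = 0.415) were not called (Tsc22d3 was, with -0.80, without control LPS replicate 3). Of oxidative stress genes, 9 of 23 had negative and 0 positive differences (14 adjusted over the list alone, median -0.26, adjusted p = 7.82e-08), with Txnrd1 (-0.66 ± 0.064) and Gclm (-0.59 ± 0.075) as examples. Of unfolded protein response genes, 7 of 21 had negative and 0 positive differences (11 adjusted over the list alone, median -0.21, adjusted p = 8.72e-05, adjusted p = 0.155 with an estimated correlation). Of interferon-stimulated genes, 6 of 57 had positive and 1 negative differences (7 adjusted over the list alone, median 0.07, adjusted p = 0.00186, adjusted p = 0.626 with an estimated correlation). Scaling gave 325 positive and 282 negative differences.

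In wild-type RAW264.7 cells that had 16 h of ethanol, LPS raised Il1b (11.74 ± 0.067) from 0.0938 ± 0.0859 to 3731 ± 243 TPM. Cxcl2 (12.35 ± 0.23), Il1a (10.76 ± 0.06), Acod1 (10.76 ± 0.039), which makes itaconate, Csf3 (9.86 ± 0.043), Ccl5 (9.71 ± 0.11) and Tnf (6.35 ± 0.064) rose too. Nos2 and Il6 were listed at 0 TPM in the vehicle libraries and had 87.2 ± 4.51 and 30.5 ± 1.66 TPM with LPS. Of LPS-induced cytokines and chemokines, 22 of 22 rose (22 adjusted over the list alone, median 7.21, adjusted p = 1.41e-29). Of interferon-stimulated genes, 54 of 55 rose and 0 fell (54 adjusted over the list alone, median 3.84, adjusted p = 3.73e-47), with Isg15 (7.14 ± 0.14), Cxcl10 (6.92 ± 0.15) and Ifit1 (6.72 ± 0.082) among them. Of feedback inhibitors, 21 of 23 rose and 1 fell (22 adjusted over the list alone, median 3.11, adjusted p = 9.81e-22). Of DNA replication and mitosis genes, 45 of 45 fell (45 adjusted over the list alone, median -1.57, adjusted p = 1.1e-10, adjusted p = 0.128 with an estimated correlation), including Tk1 (-3.82 ± 0.068), E2f2 (-3.18 ± 0.049) and Mki67 (-2.17 ± 0.086). By limma 1561 of 8964 tested genes rose and 5921 fell. All genes together had a median of -0.38, which scaling moved by 0.38, and relative to the typical gene the values are higher by that amount. With scaling 3478 genes rose and 3423 fell.

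Dex for 16 h raised the lipid chaperone Fabp4 (6.56 ± 0.066) from 2.90 ± 0.272 to 366 ± 15.7 TPM under LPS. The lipocalin Lcn2 (3.41 ± 0.051), the kinase Sgk1 (2.70 ± 0.14), Klf9 (1.55 ± 0.069), Tsc22d3 (1.54 ± 0.13) and Fkbp5 (1.43 ± 0.041) rose, while Per1 (0.13 ± 0.11, adjusted p = 0.363) was not called. Of glucocorticoid-induced genes, 9 of 21 rose and 6 fell (17 adjusted over the list alone, median 0.13, adjusted p = 0.815). Il1b (-2.95 ± 0.067) fell from 3731 ± 243 to 480.3 ± 11.0 TPM, and Ccl22 (-2.94 ± 0.10), Il1a (-2.40 ± 0.06), Nos2 (-1.33 ± 0.067) and Il6 (-1.31 ± 0.066) fell with it. Among LPS-induced cytokines and chemokines, 17 of 22 fell and 3 rose (20 adjusted over the list alone, median -0.97, adjusted p = 4.28e-13). Of interferon-stimulated genes, 53 of 55 fell and 0 rose (54 adjusted over the list alone, median -0.93, adjusted p = 1.09e-44), led by Ifit2 (-2.92 ± 0.26), Ifit3b (-2.87 ± 0.10), Ifit3 (-2.53 ± 0.10) and Rsad2 (-2.37 ± 0.092). Of cholesterol synthesis genes, 17 of 20 fell and 1 rose (18 adjusted over the list alone, median -0.37, adjusted p = 4.1e-10). Among DNA replication and mitosis genes, 45 of 45 rose (45 adjusted over the list alone, median 0.50, adjusted p = 1.3e-17). By limma 3159 of 8964 tested genes rose and 1107 fell, and after scaling 1773 rose and 2086 fell.

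Setd1a itself (ENSMUSG00000042308, chromosome 7, 127776670 to 127800122) was lower in the Setd1aDel cells of this experiment. It went from 39.0 ± 7.18 to 24.7 ± 3.65 TPM in vehicle (-0.63 ± 0.15, adjusted p = 0.00226), from 26.7 ± 3.33 to 16.1 ± 0.890 TPM with LPS (-0.70 ± 0.15, adjusted p = 0.00075) and from 25.7 ± 2.76 to 16.6 ± 3.14 TPM with Dex and LPS (-0.61 ± 0.15, adjusted p = 0.00183). In vehicle genes that were higher included Spink5 (5.70 ± 0.047), from 1.12 ± 0.0675 to 109 ± 3.02 TPM, the scavenger receptor Msr1 (4.25 ± 0.042), the small heat shock protein Hspb8 (4.03 ± 0.10), the lysozyme Lyz2 (3.93 ± 0.086) and the protease inhibitor Slpi (3.73 ± 0.18). The cyclophilin Ppic was listed at 0 TPM in the Setd1aDel libraries and had 22.6 ± 1.03 TPM in wild type. Gpnmb (-4.89 ± 0.064), S1pr1 (-3.33 ± 0.048), the efferocytosis receptor Axl (-3.31 ± 0.061) and Igf2r (-3.16 ± 0.05) were lower. Of macrophage identity genes, 21 of 26 were higher and 1 was lower (22 adjusted over the list alone, median 0.53, adjusted p = 1.5e-17). Of cholesterol synthesis genes, 20 of 20 were lower (20 adjusted over the list alone, median -0.59, adjusted p = 3.28e-09, adjusted p = 0.092 with an estimated correlation), Lss (-0.92 ± 0.053) among them. By limma 1368 of 8964 tested genes were higher and 2953 were lower, with 5079 genes not overlapping (56.66%, against 10% by chance), and after scaling 1973 were higher and 1883 lower.

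Under LPS interferon-stimulated genes were lower in the Setd1aDel cells: 54 of 55 were lower and 1 was higher (55 adjusted over the list alone, median -1.44, adjusted p = 1.03e-18, adjusted p = 0.134 with an estimated correlation). Cxcl10 (-3.40 ± 0.15), an interferon-induced chemokine, went from 526 ± 22.6 to 49.0 ± 4.40 TPM and Ifit1 (-1.29 ± 0.082) (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) from 159 ± 2.27 to 64.3 ± 2.97 TPM. The antiviral Rsad2 (-3.40 ± 0.092), Ifit2 (-3.33 ± 0.26), Cmpk2 (-3.15 ± 0.076) and the transcription factor Irf1 (-2.56 ± 0.18) were lower. Of antigen presentation genes, 13 of 16 were lower and 2 were higher (15 adjusted over the list alone, median -1.13, adjusted p = 0.00193, adjusted p = 0.171 with an estimated correlation). The cytokines split, with Csf2 (3.97 ± 0.085) and Il6 (1.48 ± 0.066) higher, Nos2 (-1.15 ± 0.067) lower and Tnf (-0.06 ± 0.064, adjusted p = 0.472) not called. Of LPS-induced cytokines and chemokines, 14 of 22 were higher and 5 were lower (19 adjusted over the list alone, median 0.29, adjusted p = 5.09e-05, adjusted p = 0.171 with an estimated correlation). Slpi (5.73 ± 0.18) went from 37.4 ± 1.62 to 2039 ± 37.8 TPM, and Serpinb2 (5.35 ± 0.06), S100a8 (4.05 ± 0.13) and Il13ra2 (3.99 ± 0.07) were higher. Of unfolded protein response genes, 18 of 22 were higher and 1 was lower (19 adjusted over the list alone, median 0.36, adjusted p = 4.45e-10, adjusted p = 0.0797 with an estimated correlation), with Ddit3 (1.34 ± 0.091) and Dnajb9 (1.27 ± 0.068) as examples. Of glucocorticoid-induced genes, 14 of 21 were higher and 3 were lower (18 adjusted over the list alone, median 0.58, adjusted p = 5.04e-07). By limma 1568 of 8964 tested genes were higher and 3798 were lower. The median over all genes was -0.11, which scaling moved by 0.10, and with scaling 2394 were higher and 2676 lower.

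With 16 h of Dex and LPS the deletion difference in interferon-stimulated genes had a lower median than with LPS alone: 54 of 55 were lower and 1 was higher (55 adjusted over the list alone, median -2.60, adjusted p = 1.52e-22, adjusted p = 0.0851 with an estimated correlation). Ifi44l (-4.33 ± 0.12), Cxcl10 (-4.29 ± 0.15), Usp18 (-4.17 ± 0.12), Oasl2 (-4.15 ± 0.17), Xaf1 (-4.05 ± 0.19) and Ifit1 (-2.50 ± 0.082) were lower, and Slpi (4.85 ± 0.18), Csf2 (4.58 ± 0.085) and Il1b (1.52 ± 0.067) higher. By limma 1521 of 8964 tested genes were higher and 4266 were lower. All genes together had a median of -0.14, moved by 0.14 with scaling, which gave 2722 higher and 2702 lower genes.

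The LPS response differed between the genotypes for 2996 genes. Serpinb2 (5.35 ± 0.085), Timp1 (4.26 ± 0.091), S100a8 (4.22 ± 0.18) and Csf2 (4.16 ± 0.12) rose more in Setd1aDel cells, and Ifit2 (-4.00 ± 0.36), Cxcl10 (-3.99 ± 0.22), Mx1 (-3.21 ± 0.22), Rsad2 (-3.12 ± 0.13) and Irf1 (-2.48 ± 0.25) rose less. Of interferon-stimulated genes, 52 of 55 had negative and 0 positive differences (53 adjusted over the list alone, median -1.38, adjusted p = 4.14e-30). Of antigen presentation genes, 15 of 16 had negative and 1 positive differences (16 adjusted over the list alone, median -1.16, adjusted p = 4.65e-10). Of unfolded protein response genes, 19 of 22 had positive and 1 negative differences (21 adjusted over the list alone, median 0.51, adjusted p = 1.79e-11). Scaling gave 1446 positive and 1701 negative differences. Dex under LPS in Setd1aDel cells lowered Ifit1 (-3.27 ± 0.082), Cxcl10 (-2.96 ± 0.15) and Il1b (-1.76 ± 0.067). Of interferon-stimulated genes, 55 of 55 fell (55 adjusted over the list alone, median -1.97, adjusted p = 2.14e-58). In all 2673 of 8964 tested genes rose and 1333 fell, and scaling gave 2025 and 1939. This response to 16 h of Dex differed between the genotypes for 946 genes. Negative differences included Xaf1 (-2.53 ± 0.27), Oas3 (-2.43 ± 0.19), Usp18 (-2.20 ± 0.17), Irf7 (-2.13 ± 0.17) and Ifit1 (-1.21 ± 0.12), and Fabp4 (-2.31 ± 0.094), Lcn2 (-0.75 ± 0.071), Sgk1 (-0.78 ± 0.19) and Mt2 (-0.98 ± 0.10) among genes that Dex raised in wild type. Positive differences included Tgtp2 (1.71 ± 0.12), Il1b (1.19 ± 0.094) and Il1a (0.99 ± 0.085). Of interferon-stimulated genes, 38 of 55 had negative and 2 positive differences (41 adjusted over the list alone, median -0.96, adjusted p = 1.13e-28, adjusted p = 0.0733 with an estimated correlation). Of glucocorticoid-induced genes, 9 of 21 had negative and 0 positive differences (15 adjusted over the list alone, median -0.31, adjusted p = 4.01e-06). The split of 258 positive and 688 negative differences became 511 and 475 with scaling.

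**Figure D1:**
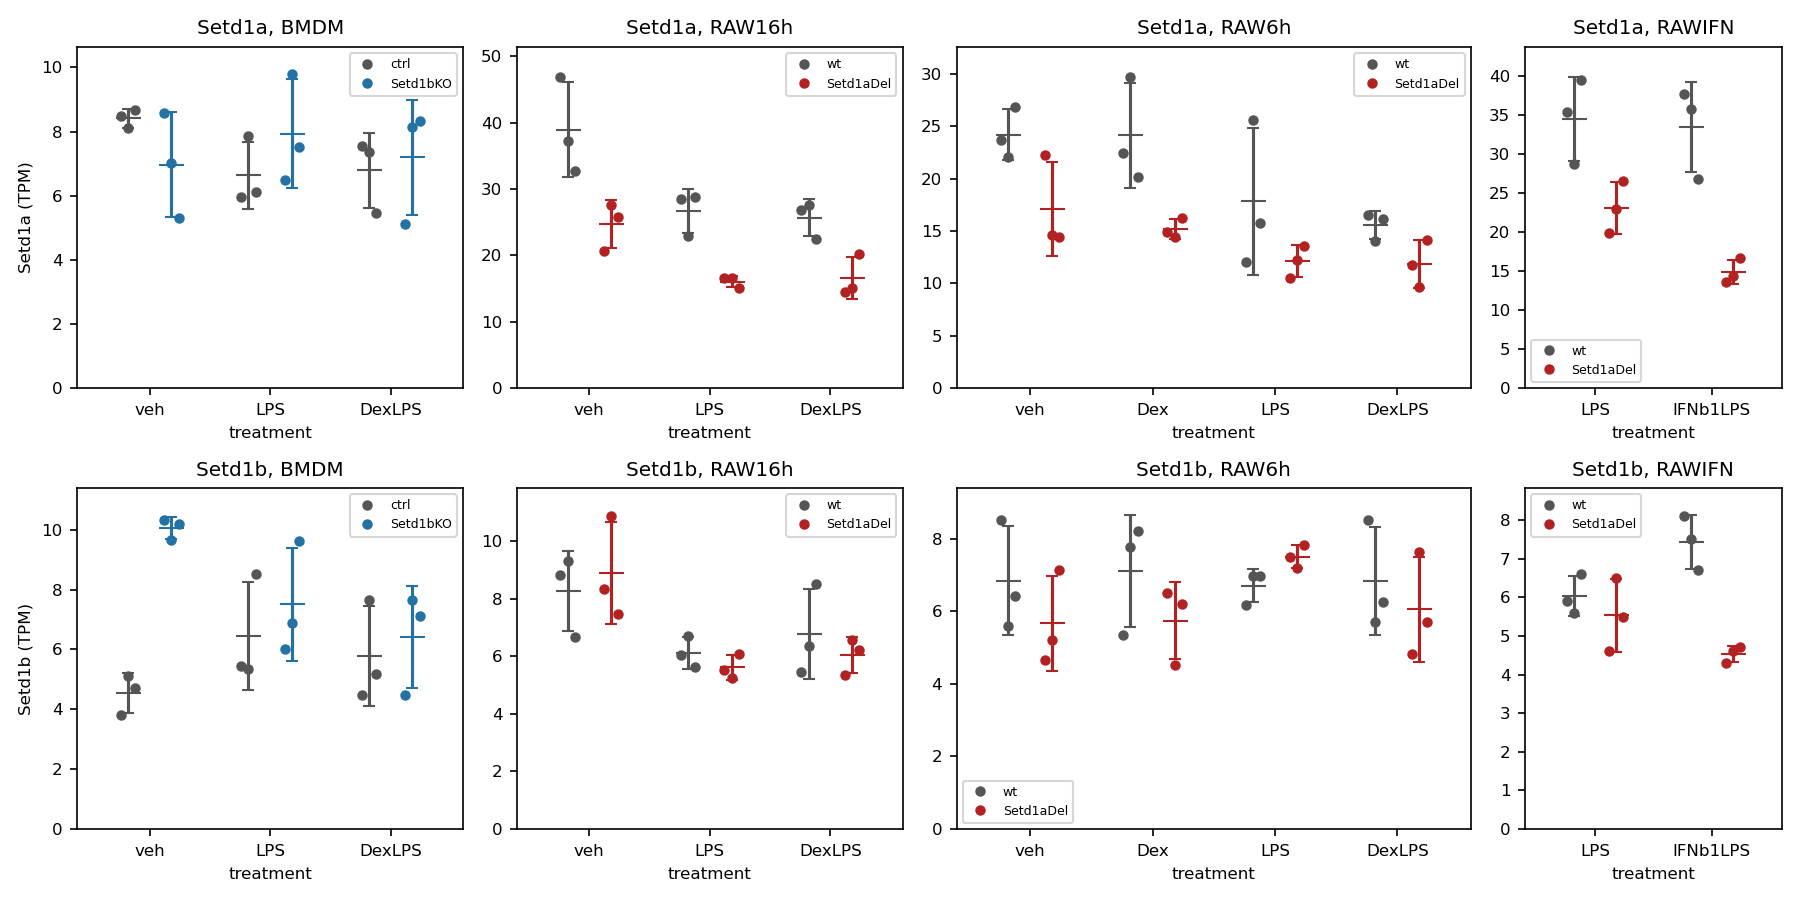
TPM of Setd1a and Setd1b in each library of the 4 experiments by treatment and genotype, on axes that start at 0, with bars at the group means and their SD (n = 3). Setd1b had a mean of 4.54 TPM in control vehicle libraries and 10.1 TPM in those labelled Setd1bKO, and Setd1a 39.0 and 24.7 TPM in wild-type and Setd1aDel vehicle libraries of the 16 h experiment.

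In the RAW264.7 experiment with 6 h of ethanol, LPS raised Il1b (9.76 ± 0.10), Ccl5 (9.32 ± 0.23), Csf3 (8.87 ± 0.20) and Tnf (3.69 ± 0.074) in wild-type cells. Ifit1 (8.58 ± 0.10) went from 0.143 ± 0.0405 to 437 ± 11.0 TPM, and Isg15 (9.07 ± 0.19), Ifit3 (8.65 ± 0.13) and the sensor Zbp1 (8.02 ± 0.14) rose with it. Of interferon-stimulated genes, 55 of 55 rose (55 adjusted over the list alone, median 4.97, adjusted p = 1.15e-54). Among LPS-induced cytokines and chemokines, 21 of 22 rose and 1 fell (22 adjusted over the list alone, median 5.31, adjusted p = 5.93e-24). Of DNA replication and mitosis genes, 45 of 45 fell (45 adjusted over the list alone, median -1.76, adjusted p = 4.74e-18), Tk1 (-4.22 ± 0.075) and Mki67 (-2.07 ± 0.086) among them. By limma 1751 of 8981 tested genes rose and 4700 fell. The median over all genes was -0.24, which scaling moved by 0.24, and with scaling 3072 rose and 3038 fell.

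Dex given for 6 h with LPS raised Tsc22d3 (3.52 ± 0.10) from 4.44 ± 0.196 to 61.5 ± 3.65 TPM, and Fabp4 (4.89 ± 0.16), the haptoglobin gene Hp (3.02 ± 0.091), Lcn2 (2.81 ± 0.15), Dusp1 (2.51 ± 0.084), Klf9 (2.27 ± 0.084), Fkbp5 (1.73 ± 0.064) and Per1 (1.24 ± 0.17) rose too. Of glucocorticoid-induced genes, 13 of 22 rose and 4 fell (17 adjusted over the list alone, median 0.62, adjusted p = 2.02e-07). Il1b (-3.50 ± 0.10) fell from 895 ± 20.8 to 78.3 ± 2.63 TPM, and Il1a (-3.04 ± 0.072), Lif (-2.46 ± 0.12), Ccl22 (-2.29 ± 0.28), Il6 (-1.87 ± 0.072), Nos2 (-1.69 ± 0.058) and Tnf (-0.37 ± 0.074) fell. Of LPS-induced cytokines and chemokines, 17 of 22 fell and 3 rose (20 adjusted over the list alone, median -1.11, adjusted p = 5.31e-15). Of interferon-stimulated genes, 51 of 55 fell and 0 rose (53 adjusted over the list alone, median -0.70, adjusted p = 1.23e-38), with Ifit3b (-2.13 ± 0.10), Rsad2 (-1.98 ± 0.073) and Ifit1 (-1.63 ± 0.10) as examples. By limma 1320 of 8981 tested genes rose and 953 fell, and after scaling 999 rose and 1245 fell. Without LPS, 6 h of Dex raised Tsc22d3 (4.10 ± 0.10) from 9.74 ± 1.44 to 183 ± 7.85 TPM, along with Fabp4 (4.14 ± 0.16), Per1 (2.47 ± 0.17), Sgk1 (2.35 ± 0.23), Fkbp5 (2.25 ± 0.064), Klf9 (1.94 ± 0.084) and Dusp1 (1.92 ± 0.084). Of glucocorticoid-induced genes, 15 of 22 rose and 1 fell (16 adjusted over the list alone, median 1.01, adjusted p = 5.45e-17). Plau (-2.60 ± 0.041), Ltb (-2.12 ± 0.12), Cxcl14 (-1.89 ± 0.16), Tnf (-0.97 ± 0.074) and Tk1 (-0.84 ± 0.075) fell. Among DNA replication and mitosis genes, 39 of 45 fell and 0 rose (40 adjusted over the list alone, median -0.41, adjusted p = 6.89e-15). In all 1080 of 8981 tested genes rose and 2223 fell, and scaling gave 1423 and 1759.

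Setd1a was not called in any of the 4 treatments of the 6 h experiment. It went from 24.2 ± 2.44 to 17.1 ± 4.48 TPM between wild-type and Setd1aDel vehicle libraries (-0.50 ± 0.21, adjusted p = 0.0954), and its change was -0.46 ± 0.21 with LPS (adjusted p = 0.126), -0.38 ± 0.21 with Dex and LPS (adjusted p = 0.196) and -0.62 ± 0.21 with Dex (adjusted p = 0.0557). Leaving out 1 library gave a call in 3 of these: without Setd1aDel vehicle replicate 1 (-0.69), wild-type LPS replicate 1 (-0.69) and wild-type Dex replicate 3 (-0.73), and fitting only the compared groups gave one with Dex (-0.62). In vehicle the Setd1aDel cells had more of the heat shock protein Hspb8 (4.67 ± 0.09), of Vegfc (2.42 ± 0.10) and Ece1 (2.07 ± 0.16) and of the interferon-stimulated Irf7 (2.55 ± 0.091), Ifi44 (2.00 ± 0.11), Trim30a (1.82 ± 0.10) and Oasl1 (1.52 ± 0.10). Of interferon-stimulated genes, 27 of 55 were higher and 0 were lower (27 adjusted over the list alone, median 0.29, adjusted p = 4.21e-19). The lysozyme Lyz1 (-6.14 ± 0.17) was lower, from 298 ± 5.48 to 3.29 ± 0.757 TPM, as were Anpep (-2.41 ± 0.064), Egr1 (-2.10 ± 0.12) and the chaperone Hspa5 (-1.26 ± 0.23), and Ppic was listed at 0 TPM against 15.9 ± 0.723 TPM in wild type. Of antigen presentation genes, 9 of 16 were higher and 1 was lower (10 adjusted over the list alone, median 0.38, adjusted p = 7.34e-09). Of unfolded protein response genes, 13 of 22 were lower and 3 were higher (17 adjusted over the list alone, median -0.35, adjusted p = 0.000108). By limma 591 of 8981 tested genes were higher and 1400 were lower, and after scaling 975 were higher and 717 lower.

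Under LPS Hspb8 (4.94 ± 0.09), Vegfc (2.67 ± 0.10), Csf2 (2.13 ± 0.19), Slpi (2.04 ± 0.094) and Serpinb2 (1.67 ± 0.10) were higher, and Lyz1 (-5.32 ± 0.17), Ass1 (-3.86 ± 0.076), Egr1 (-2.93 ± 0.12) and Axl (-1.18 ± 0.10) lower. Interferon-stimulated genes went both ways, with Trim30a (1.48 ± 0.10) and Ifit1 (0.45 ± 0.10) higher, Rsad2 (-0.74 ± 0.073) and Slfn1 (-0.71 ± 0.064) lower and Cxcl10 (-0.21 ± 0.32, adjusted p = 0.702) not called, and Ifit1 (0.45) and Rsad2 (-0.74) were not called with a pseudocount of 0.1. Of that list, 12 of 55 were lower and 6 were higher (25 adjusted over the list alone, median -0.08, adjusted p = 0.162). Of unfolded protein response genes, 15 of 22 were lower and 0 were higher (16 adjusted over the list alone, median -0.53, adjusted p = 2.88e-13), among them Sdf2l1 (-0.93 ± 0.07), Pdia4 (-0.86 ± 0.055) and Manf (-0.80 ± 0.054). Of DNA replication and mitosis genes, 23 of 45 were higher and 0 were lower (30 adjusted over the list alone, median 0.17, adjusted p = 1.2e-11). By limma 825 of 8981 tested genes were higher and 1109 were lower, with 3501 not overlapping (38.98%, against 10% by chance), and scaling gave 1098 and 957. With Dex and LPS, the Setd1aDel cells had lower interferon-stimulated genes, since 45 of 55 were lower and 1 was higher (50 adjusted over the list alone, median -0.55, adjusted p = 4.14e-24). Rsad2 (-1.70 ± 0.073), Cmpk2 (-1.10 ± 0.095) and Ccl5 (-1.28 ± 0.23) were lower there, Hspb8 (4.87 ± 0.09), Csf2 (1.76 ± 0.19) and Slpi (2.16 ± 0.094) higher, and 1173 of 8981 tested genes were higher and 1177 were lower (1356 called with only the compared groups). With Dex alone Hspb8 (4.51 ± 0.09), Irf7 (2.09 ± 0.091) and Trim30a (2.06 ± 0.10) were higher and Tsc22d3 (-0.47 ± 0.10) and Lyz1 (-5.94 ± 0.17) lower. In all 557 of 8981 tested genes were higher and 662 were lower (668 called with only the compared groups), and scaling gave 738 and 453.

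As a difference of responses, the LPS response of the 6 h experiment differed between genotypes for 503 genes, Serpinb2 (1.67 ± 0.14) and Csf2 (1.27 ± 0.27) in the positive (Csf2 had -0.60 and was not called with a pseudocount of 0.1) and Irf7 (-2.79 ± 0.13), Lgals9 (-1.80 ± 0.14), Oasl1 (-1.58 ± 0.14) and Ccl5 (-1.49 ± 0.33) in the negative direction. Of interferon-stimulated genes, 24 of 55 had negative and 0 positive differences (35 adjusted over the list alone, median -0.46, adjusted p = 1.16e-26). Scaling turned the split of 267 positive and 236 negative differences into 190 and 327. Dex under LPS in Setd1aDel cells raised Tsc22d3 (3.06 ± 0.10) and Fkbp5 (1.63 ± 0.064) and lowered Ifit1 (-2.70 ± 0.10) and Il1b (-2.85 ± 0.10). In all 1988 of 8981 tested genes rose and 965 fell, and scaling gave 1447 and 1419. This response to 6 h of Dex differed between the genotypes for 475 genes (278 to 522 when 1 library was left out). Ifit3b (-1.19 ± 0.14), Ifit1 (-1.07 ± 0.14), Mx1 (-1.01 ± 0.18) and Ifit3 (-0.99 ± 0.18) fell further with Dex in Setd1aDel cells, but with a pseudocount of 0.1 these 4 were not called (-1.29, -1.07, -1.06 and -1.001). Dusp1 (-0.59 ± 0.12) had a negative difference, Pdia4 (0.71 ± 0.078) and Dcstamp (1.09 ± 0.18) had positive differences, and those of Tsc22d3 (-0.46 ± 0.14, adjusted p = 0.0594) and Fkbp5 (-0.11 ± 0.09, adjusted p = 0.561) were not called (Tsc22d3 was, with -0.56, without Setd1aDel LPS replicate 2). Of interferon-stimulated genes, 28 of 55 had negative and 0 positive differences (38 adjusted over the list alone, median -0.49, adjusted p = 1.48e-31). Of unfolded protein response genes, 10 of 22 had positive and 0 negative differences (15 adjusted over the list alone, median 0.31, adjusted p = 2.55e-09). Of glucocorticoid-induced genes, 5 of 22 had negative and 1 positive differences (9 adjusted over the list alone, median -0.17, adjusted p = 0.00114). Scaling turned 292 positive and 183 negative differences into 233 and 238. Without LPS the Dex response differed for 26 genes (9 to 42 when 1 library was left out), among them Stk17b (-0.50 ± 0.069) and Cd14 (-0.32 ± 0.048) in the negative direction. Scaling turned 17 positive and 9 negative differences into 9 and 12.

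**Figure D2:**
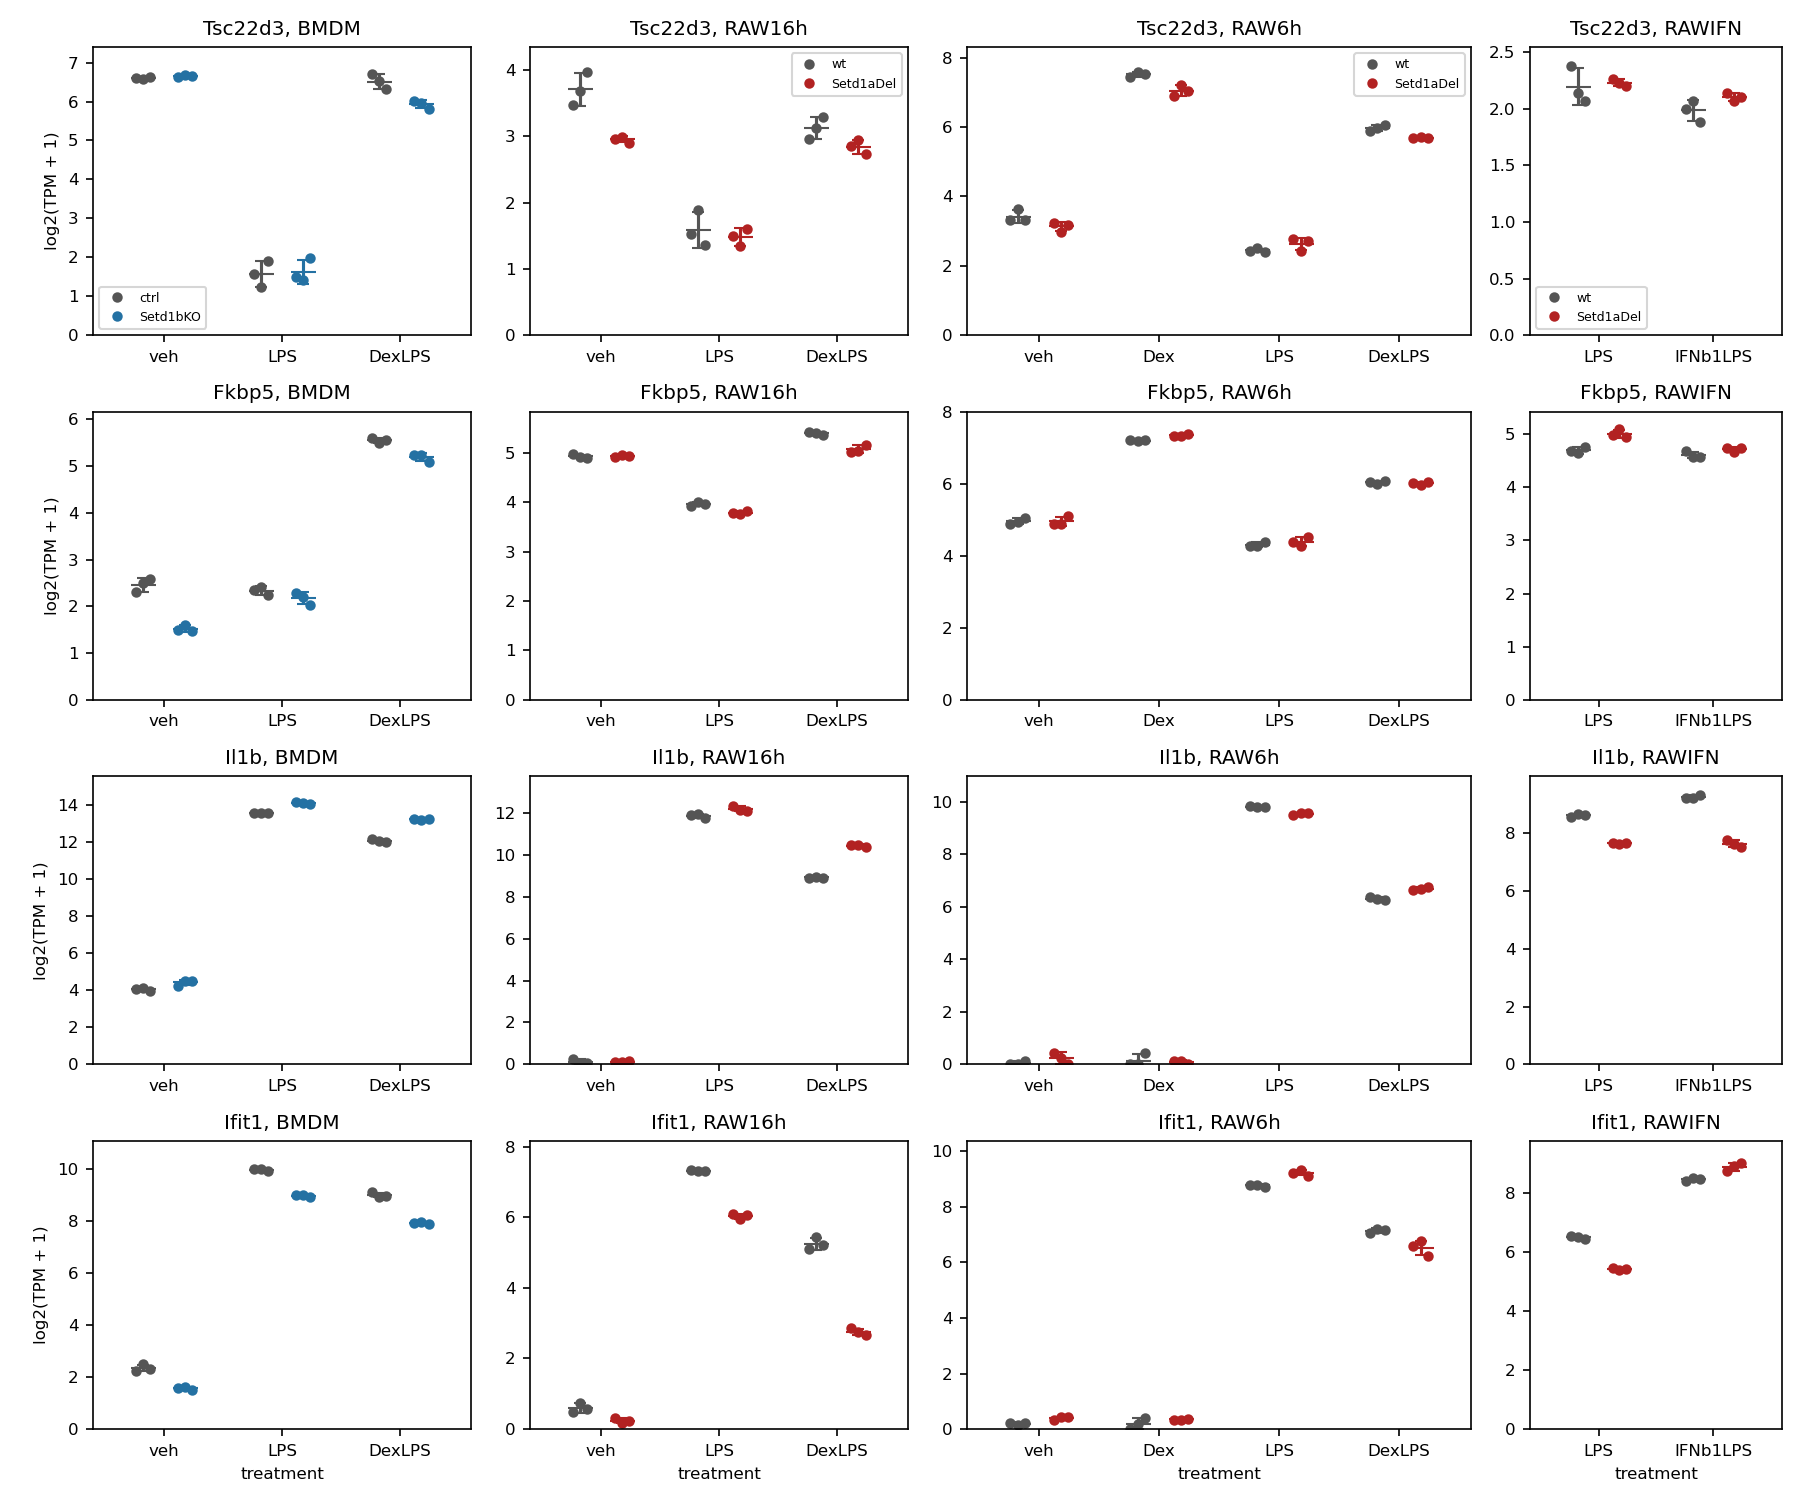
Log2(TPM + 1) of Tsc22d3, Fkbp5, Il1b and Ifit1 in each library of the 4 experiments, by treatment and genotype, on axes that start at 0, with bars at group means and their SD (n = 3). Tsc22d3 had 90.9 TPM in control marrow-derived macrophages with Dex and LPS, 7.79 TPM in the wild-type 16 h RAW264.7 experiment and 61.5 TPM in the 6 h experiment, and the marrow-derived and RAW264.7 values come from tables that were normalized separately.

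The RAW264.7 experiments were compared as differences of effects, each effect taken within its own experiment. In wild-type cells the Dex response under LPS differed between 16 h and 6 h for 1213 genes. Glucocorticoid targets had lower changes at 16 h, with Dusp1 (-2.57 ± 0.10), Tsc22d3 (-1.98 ± 0.17), Per1 (-1.11 ± 0.22), Klf9 (-0.72 ± 0.11) and Fkbp5 (-0.30 ± 0.077), and the clock gene Cry1 (-1.72 ± 0.085) and Rgs2 (-1.47 ± 0.25) did the same. Fabp4 (1.67 ± 0.19) and Slpi (1.82 ± 0.20) had higher changes. Of glucocorticoid-induced genes, 11 of 22 had negative and 3 positive differences (17 adjusted over the list alone, median -0.31, adjusted p = 3.76e-09). Of interferon-stimulated genes, 18 of 55 had negative and 2 positive differences (24 adjusted over the list alone, median -0.28, adjusted p = 3.19e-12, adjusted p = 0.0877 with an estimated correlation). Scaling turned 821 positive and 392 negative differences into 486 and 678.

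The deletion effect under LPS, a contrast added after the data were seen, differed between 16 h and 6 h for 3713 genes. Lyz1 (6.48 ± 0.24), S100a8 (4.69 ± 0.18), Slpi (3.69 ± 0.20) and Il6 (1.46 ± 0.10) had higher deletion effects at 16 h, and Cxcl10 (-3.19 ± 0.38), Ifit2 (-3.12 ± 0.47), Mx1 (-3.04 ± 0.20), Irf1 (-2.07 ± 0.31), Ifit1 (-1.74 ± 0.14) and Nos2 (-1.69 ± 0.084) lower ones. Of interferon-stimulated genes, 52 of 55 had negative and 1 positive differences (53 adjusted over the list alone, median -1.44, adjusted p = 8.72e-28). Unfolded protein response genes went the other way, in that 20 of 22 had positive and 1 negative differences (21 adjusted over the list alone, median 0.89, adjusted p = 2.94e-21). Among DNA replication and mitosis genes, 44 of 45 had negative and 0 positive differences (44 adjusted over the list alone, median -0.52, adjusted p = 9.81e-16). Scaling gave 1642 positive and 1843 negative differences.

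IFNB1 added to LPS raised interferon-stimulated genes in wild-type RAW264.7 cells. The GTPase Gbp2 (3.45 ± 0.10) went from 2.33 ± 0.208 to 35.4 ± 1.95 TPM and Cxcl10 (2.99 ± 0.08) from 149 ± 16.7 to 1186 ± 20.7 TPM. Gbp2b (3.42 ± 0.10), Tgtp2 (3.29 ± 0.14), Iigp1 (2.88 ± 0.16), Mx1 (3.11 ± 0.11), Ifit1 (1.96 ± 0.059), Nos2 (1.57 ± 0.079) and Il10 (1.36 ± 0.12) rose as well. Of interferon-stimulated genes, 58 of 59 rose and 0 fell (58 adjusted over the list alone, median 1.38, adjusted p = 9.07e-78). Of antigen presentation genes, 13 of 16 rose and 0 fell (13 adjusted over the list alone, median 0.92, adjusted p = 1.1e-18). Of feedback inhibitors, 15 of 24 rose and 2 fell (18 adjusted over the list alone, median 0.37, adjusted p = 1.82e-10). The cyclin Ccne2 (-1.06 ± 0.09), Ago1 (-1.57 ± 0.35), Sirpa (-1.12 ± 0.072) and Ccl2 (-0.31 ± 0.067) fell. By limma 1038 of 10923 tested genes rose and 2571 fell, 166 and 21 of them by at least 2-fold, and after scaling 1586 rose and 1369 fell.

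In Setd1aDel cells Gbp2 (4.49 ± 0.10), Ifit3 (4.39 ± 0.058), Cxcl10 (4.09 ± 0.08), Il10 (3.56 ± 0.12) and Ifit1 (3.47 ± 0.059) rose, and 1145 of 10923 tested genes rose and 4763 fell. Of immediate early and dissociation stress genes, 9 of 15 rose and 3 fell (12 adjusted over the list alone, median 0.27, adjusted p = 3.81e-05). All genes together had a median of -0.18, which scaling moved by 0.17, and with scaling 2390 rose and 2184 fell. The IFNB1 response differed between genotypes for 1237 genes (553 to 1876 when 1 library was left out). Isg20 (1.85 ± 0.13), Ifit3 (1.83 ± 0.082), Ifit1 (1.51 ± 0.083), Irf1 (1.19 ± 0.10) and Cxcl10 (1.10 ± 0.11) rose more in Setd1aDel cells, Slfn3 (-2.80 ± 0.29), Il1a (-0.99 ± 0.078) and Il1b (-0.64 ± 0.078) had negative differences, and Ifnb1 was not called (-0.25 ± 0.23, adjusted p = 0.513). Of interferon-stimulated genes, 52 of 59 had positive and 0 negative differences (56 adjusted over the list alone, median 0.82, adjusted p = 2.86e-77). Of mitochondrially encoded transcripts, 3 of 15 had negative and 0 positive differences (5 adjusted over the list alone, median -0.50, adjusted p = 0.00747, adjusted p = 0.55 with an estimated correlation). Scaling turned 362 positive and 875 negative differences into 621 and 314.

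Setd1a was lower in the Setd1aDel cells of the IFNB1 experiment, from 34.5 ± 5.40 to 23.1 ± 3.35 TPM with LPS (-0.56 ± 0.15, adjusted p = 0.0116) and from 33.4 ± 5.77 to 14.9 ± 1.55 TPM with IFNB1 and LPS (-1.10 ± 0.15, adjusted p = 0.00011). With LPS alone Hspb8, Ccnd2 and Cd24a were listed at 0 TPM in the wild-type libraries and had 60.6 ± 1.16, 45.2 ± 2.57 and 43.1 ± 0.416 TPM in Setd1aDel libraries. Cd24a lies in a stretch of chromosome 10 where 38 of 41 neighbouring genes had higher values in Setd1aDel cells of this experiment. Ly6e (4.70 ± 0.071) went from 52.3 ± 6.73 to 1381 ± 31.0 TPM and the monocyte attractant Ccl2 (3.51 ± 0.067) from 27.6 ± 3.26 to 324 ± 12.7 TPM, and Il1rn (3.87 ± 0.10), Csf2 (3.68 ± 0.094), Csf3 (2.31 ± 0.046), Ccl5 (1.83 ± 0.061) and Il6 (1.36 ± 0.11) were higher. Interferon beta itself was lower, Ifnb1 (-2.44 ± 0.16), from 12.3 ± 0.557 to 1.47 ± 0.289 TPM. Isg20 (-2.21 ± 0.089), Irf1 (-1.96 ± 0.073), Cxcl10 (-1.78 ± 0.08), Ifit1 (-1.08 ± 0.059), Adgre1 (-2.27 ± 0.055), Fcgr1 (-1.66 ± 0.053) and Il1b (-0.97 ± 0.055) were lower too. Of interferon-stimulated genes, 43 of 59 were lower and 5 were higher (49 adjusted over the list alone, median -0.69, adjusted p = 2.1e-13, adjusted p = 0.155 with an estimated correlation). Among LPS-induced cytokines and chemokines, 20 of 28 were higher and 4 were lower (25 adjusted over the list alone, median 0.88, adjusted p = 9.07e-10, adjusted p = 0.0628 with an estimated correlation). By limma 1934 of 10923 tested genes were higher and 2715 were lower, and scaling gave 2300 and 2249.

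With IFNB1 added, Il1rn (4.53 ± 0.10), Ccl2 (4.16 ± 0.067), Csf2 (4.14 ± 0.094), Il10 (3.37 ± 0.12) and Il6 (2.18 ± 0.11) were higher, Ifit1 (0.43 ± 0.059) was higher and Irf1 (-0.77 ± 0.073), Cxcl10 (-0.69 ± 0.08), Ifnb1 (-2.69 ± 0.16) and Il1b (-1.61 ± 0.055) lower. Of interferon-stimulated genes, 29 of 59 were higher and 15 were lower (44 adjusted over the list alone, median 0.07, adjusted p = 9.78e-05, adjusted p = 0.322 with an estimated correlation). Of LPS-induced cytokines and chemokines, 21 of 28 were higher and 3 were lower (24 adjusted over the list alone, median 0.98, adjusted p = 8.09e-15). By limma 1725 of 10923 tested genes were higher and 4190 were lower. The median over all genes was -0.14, which scaling moved by 0.13, and with scaling 2621 were higher and 2369 lower.

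**Figure D3:**
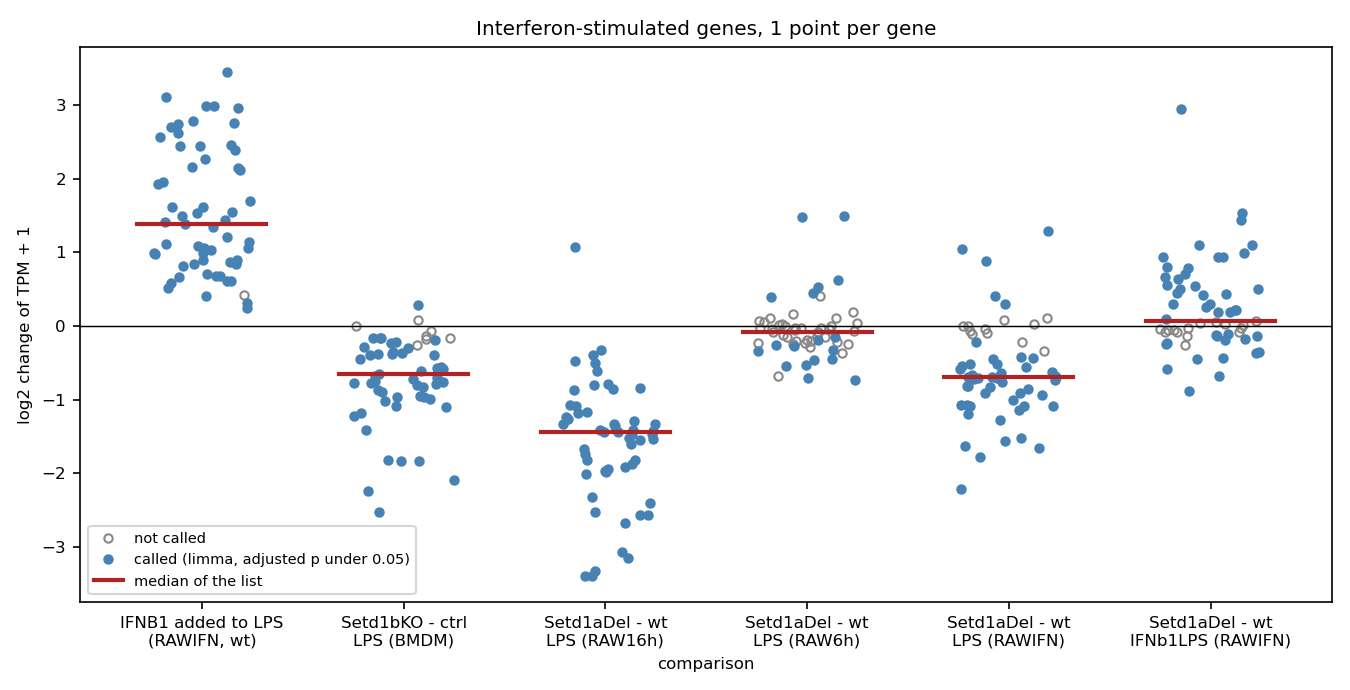
Log2 change of each interferon-stimulated gene in 6 comparisons: IFNB1 added to LPS, the libraries labelled Setd1bKO against control with LPS, and Setd1aDel against wild type with LPS in each of 3 experiments and with IFNB1 and LPS (1 point per gene, filled where limma called it, with a line at 0 and bars at the median). For the deletion with LPS the medians were -1.44 in the 16 h experiment, -0.08 in the 6 h experiment and -0.69 in the experiment with IFNB1.

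Across the 3 RAW264.7 experiments the deletion effect under LPS was called in the same direction for 646 of 8816 genes tested in all of them. Of these, 248 were higher, against 26.67 if the calls were independent, and 398 were lower, against 120.4. By at least 2-fold in each experiment 22 genes were higher and 5 lower. The higher ones included Hspb8 (4.95 ± 0.10), Csf2 (3.97 ± 0.085) and Slpi (5.73 ± 0.18), each with the value of the 16 h experiment, and the lower ones Axl (-3.96 ± 0.061) and Ighm (-3.75 ± 0.07). The effects correlated across genes, which are not independent replicates, with Pearson's r of 0.311 between the 16 h and 6 h experiments, 0.472 between the 16 h and IFNB1 experiments and 0.382 between the other two. Of 1388 genes called in both the 16 h and 6 h experiments, 430 had opposite directions (30.98%). Of the 55 interferon-stimulated genes tested in all 3, 54 were lower and 1 higher with the deletion at 16 h, 12 lower and 6 higher at 6 h, and 41 lower and 5 higher in the IFNB1 experiment. The deletion effect under LPS was also set against the IFNB1 effect of wild-type cells across genes. In the 6 h experiment r was -0.00577, and the 115 genes that IFNB1 raised at least 2-fold had a median deletion effect of -0.08. In the 16 h experiment r was -0.169 and the median -1.33. In the IFNB1 experiment the effects share the wild-type LPS libraries, which adds covariance by itself: the covariance was 0.0271, against 0.0187 from simulated noise alone, a difference of 0.00844. The 166 genes raised at least 2-fold there had a median of -0.21.

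Sets chosen by the wild-type Dex response of 1 experiment were tested for a genotype difference of the Dex response in another. Each Dex set held called genes that changed at least 2-fold, and the choice and the test used separate libraries. In the 16 h RAW264.7 experiment, 59 genes that Dex raised at least 2-fold at 6 h had a median difference of -0.24, against -0.03 for all genes (camera, adjusted p = 0.000116). Their median Dex response was 1.05 in wild-type and 0.81 in Setd1aDel cells, 17 had a called negative and 0 a called positive difference. In the 6 h experiment, 116 genes that 16 h of Dex lowered had a median difference of -0.29, against 0.02 for all genes (adjusted p = 4.66e-12), with a median Dex response of -0.91 in wild-type and -1.29 in Setd1aDel cells. In the marrow-derived cells, 100 of those genes had a median difference of 0.12 (adjusted p = 0.000116, adjusted p = 0.244 with an estimated correlation). The genes that 16 h of Dex raised were not called in the 6 h experiment (median 0.02, mean -0.08, adjusted p = 0.0907, but called with -0.0447 after scaling, 0.0460 with another fold minimum, -0.00216 without Setd1aDel LPS replicate 2 and -0.00784 without Setd1aDel Dex and LPS replicate 3) or in the marrow-derived cells (adjusted p = 0.489), nor were the genes that 6 h of Dex lowered in the 16 h experiment (median -0.02 against -0.03 for all genes, mean -0.07, test direction up, adjusted p = 0.489). The 889 tested genes that IFNB1 raised in wild-type cells had a median deletion effect under LPS of -0.08 in the 6 h experiment (adjusted p = 0.0282, adjusted p = 0.419 with an estimated correlation). At 16 h their median was -0.23, which was not called (adjusted p = 0.0837), and the 115 raised at least 2-fold had a median of -1.33.

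The 3 experiments with Dex under LPS shared 8283 genes. In control or wild-type cells Dex raised 560 in each, against 186.2 if calls were independent, and lowered 350, against 14.93. Counts here are unscaled, and with scaling more tested genes fell than rose in each. By at least 2-fold 12 rose in each, Tsc22d3, Fkbp5 and Fabp4 among them, and 30 fell, among them Il1b, Il6 and Nos2. Of genes that LPS raised at least 2-fold, Dex lowered 494 of 901 in marrow-derived cells, 372 of 513 in the 16 h RAW264.7 experiment and 349 of 520 in the 6 h experiment, and raised 196, 50 and 43. Both effects use the same LPS libraries, so that noise alone leans such genes towards lower with Dex. The covariances of the 2 effects were -0.223, -0.203 and -0.173, against -0.0076, -0.00468 and -0.00864 from simulated noise. COMPASS members were not called as a list in the Setd1b or 16 h Setd1a comparisons. At 16 h in vehicle 7 of 20 were lower and 1 higher, against 2953 and 1368 of 8964 tested genes. Of mitochondrially encoded transcripts, 9 of 13 were higher and 0 were lower (9 adjusted over the list alone, median 0.45, adjusted p = 0.000598, adjusted p = 0.395 with an estimated correlation) in Setd1aDel cells of the 16 h vehicle comparison, and with LPS in the IFNB1 experiment 9 of 15 were higher and 0 were lower (11 adjusted over the list alone, median 0.44, adjusted p = 0.000876, adjusted p = 0.435 with an estimated correlation), where of ribosomal protein genes 30 of 38 were lower and 0 were higher (35 adjusted over the list alone, median -0.23, adjusted p = 3.67e-07, adjusted p = 0.238 with an estimated correlation).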

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

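The splits of the samples and the test on wild-type cells were planned before their results were seen, while the tests on genotype labels, scaling and hours in ethanol and the tests on chromosome segments were chosen afterwards. Several responses differed between genotypes, or between the 16 h and 6 h experiments, by a test of the difference itself. Those 2 experiments may differ in more than the hours of treatment. In the marrow-derived cells the LPS response differed between the libraries labelled Setd1bKO and control for 2000 genes, with Csf2 (2.92 ± 0.17) up and Fcgr1 (-1.80 ± 0.16) down, and the Dex response under LPS for 569, Ms4a4a (-2.33 ± 0.16) among them. Between Setd1aDel and wild-type RAW264.7 cells the LPS response differed for 2996 genes at 16 h, Cxcl10 (-3.99 ± 0.22) among them, and for 503 at 6 h, Irf7 (-2.79 ± 0.13) among them. The Dex response under LPS differed for 946 genes at 16 h, Fabp4 (-2.31 ± 0.094) among them, and for 475 at 6 h (278 to 522 when 1 library was left out), Pdia4 (0.71 ± 0.078) among them. The Dex response without LPS differed for 26 genes (9 to 42) and the IFNB1 response for 1237 (553 to 1876). Between 16 h and 6 h the wild-type Dex response differed for 1213 genes and the deletion effect under LPS for 3713. The sets with a genotype difference of the Dex response had medians of -0.24 (genes raised by 6 h of Dex, tested at 16 h), -0.29 (genes lowered by 16 h of Dex, tested at 6 h) and 0.12 (the latter genes in the marrow-derived cells, not called with an estimated correlation).

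Other splits of the same samples gave lower counts. In the 24 comparisons of 3 against 3 libraries the real split, with 1219 to 7812 genes, gave the highest count of the 10 splits, and the others gave at most 146, but 10 splits are too few for a share under 0.05. For the differences of effects 1 of 100 splits, the real one, gave as many genes, which argues against chance at that share. The highest of the others were 2 and 3 genes for LPS and Dex in the marrow-derived cells, 1534 and 77 at 16 h, 1 and 24 at 6 h, 5 for Dex without LPS, 14 for IFNB1, and 304 and 2234 for the wild-type Dex response and the deletion effect at 16 h minus 6 h. Among the sets, 1 of 100 permutation splits, the real one, gave as low a camera p for genes raised by 6 h of Dex, tested at 16 h (3.33e-05, lowest other 5.88e-05). So it did for those lowered by 16 h of Dex, tested at 6 h (permutation splits, 5.82e-13, lowest other 6.26e-11). This argues against chance at that share only. In the marrow-derived cells 23 of 100 splits gave a p as low for the genes lowered by Dex (4.35e-05, lowest other 1.95e-13), so that chance cannot be excluded. The sets that were not called had 37 (genes raised by 16 h of Dex, marrow-derived cells), 65 (genes lowered by 6 h of Dex, at 16 h) and 13 (genes raised by 16 h of Dex, at 6 h) of 100 splits with a p as low. For the genes raised by IFNB1, with 10 splits, p was 0.0523 at 16 h against 0.176 as the lowest other, and 0.0141 at 6 h against 0.00581, with 2 splits as low.

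The deletion effect under LPS on interferon-stimulated genes had a median of -1.44 at 16 h and -0.08 at 6 h, and 52 of 55 genes had a called negative difference, Cxcl10 (-3.19 ± 0.38) and Mx1 (-3.04 ± 0.20) among them. In genes chosen in vehicle, 12 of 12 LPS libraries lay on their label's side. This argues against single exchanged labels, but exchanged groups would score alike. Scaling shifts all genes of a library nearly alike, so the list minus all genes (-1.34 with and without it) decides nothing. The list's median was -1.352 after scaling, with 50 of 55 genes called negative, which argues against scaling as the whole cause. In wild-type LPS libraries the list was lower at 16 h than at 6 h by -0.739 relative to all genes, while wild-type cells that made the effect would have had higher values there. Hours in ethanol before LPS cannot be told apart from other differences between the experiments. The IFNB1 experiment, with LPS for 6 h and no ethanol label, had 41 of 55 genes lower with the deletion, against 12 at 6 h. Culture, clone and passage stay open as well.

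Runs of neighbouring genes moved together with genotype: on chromosome 9, genes from 66843664 to 80144953 had a median of -0.31 relative to all genes in 16 h vehicle libraries, among them Cox7a2, and genes from 3403592 to 21028817 had 0.297, among them Icam1, and on chromosome 10 genes from 39612934 to 54076609, among them Snx3 and Cd24a, had 0.925 in the IFNB1 experiment with LPS. Chance order of genes gave p = 0.001 in each, the smallest that 1000 permutations can give. Of 24 windows in genotype comparisons 8 reached it, mostly these stretches again. Windows of treatment responses elsewhere did too, so it does not set the stretches apart. In comparisons not used to choose them, an effect of the deletion shared with the 6 h experiment is argued against for the stretch around Cox7a2 (0.012 at 6 h and -0.293 at 16 h, both with LPS, with -0.074 and -0.11 without and with IFNB1 in the IFNB1 experiment) and that around Snx3 (0.0236 at 6 h with LPS, 0.742 with IFNB1 and LPS), and one shared with the IFNB1 experiment for that around Icam1 (-0.0603 with LPS), while one shared by 6 h and 16 h stays open there, since the intervals met with LPS (0.125 and 0.28) but not with Dex and LPS (0.042 and 0.264). With LPS the wild-type libraries differed between 16 h and 6 h in the stretches of chromosome 9 (0.309 and -0.162), the Setd1aDel libraries by -0.0671 and -0.00388. A candidate explanation is a gain or loss of chromosome segments in the cells used, since each stretch kept its direction in the other comparisons of the same experiment (smallest size 0.264), and no DNA was analysed here.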

How the results depend on the processing

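The counts without the genes of the chromosome stretches, the comparison of deletion effects between 16 h and 6 h and the list tests under alternatives other than an estimated correlation were chosen after the data were seen. In 45 of 45 results a replicate block left the value the same. Counts stayed within 1.5 times the main count, and the sets and the correlation kept their direction and side of the threshold. With a replicate block the count for the LPS response of the marrow-derived control cells was 7814, against 7812. The same held in 44 of 45 with no filter, 44 of 45 with a pseudocount of 0.1 and 44 of 46 with scaling.

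Fitting only the compared groups gave 1356 genes for the deletion with Dex and LPS at 6 h (main 2350), 668 with Dex (1219), 305 for the difference of Dex responses under LPS (475) and 10 without LPS (26), where fewer libraries estimate the spread. Scaling turned Fkbp5 in the marrow-derived LPS response to 0.31, and the genes raised by 16 h of Dex, tested at 6 h, to -0.0447 (called, main 0.0181), and it took the IFNB1 genes at 6 h to -0.0208 (not called). A pseudocount of 0.1 turned Csf2 in the difference of LPS responses at 6 h to -0.60 and the correlation of the deletion and IFNB1 effects to 0.00655 (main -0.00577). Another fold minimum gave 0.0460 (called) for the genes raised by 16 h of Dex at 6 h, and -0.0801 (not called) and -1.33 (called, not run with an estimated correlation) for the IFNB1 genes at 6 h and 16 h. With no filter the last set was called with -0.243. With an estimated correlation 159 of 772 list tests were called against 342, and the sets with medians of 0.117 (genes lowered by Dex, marrow-derived cells) and -0.0801 (IFNB1 genes at 6 h) were no longer called. Apart from the fewer libraries in the first of these, the cause was not tested.

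Leaving out 1 library gave 278 to 522 genes for the difference of Dex responses under LPS at 6 h. The count was 287 without wild-type LPS replicate 3, 278 without wild-type Dex and LPS replicate 2, and 312 and 315 without Setd1aDel LPS replicates 1 and 2. It gave 9 to 42 for the Dex response without LPS: 9 without wild-type vehicle replicate 3, 14 and 15 without wild-type Dex replicates 1 and 2, 16 and 17 without Setd1aDel vehicle replicates 1 and 2, and 42, 13 and 10 without Setd1aDel Dex replicates 1 to 3. For the IFNB1 response the range was 553 to 1876: 561 and 572 without wild-type LPS replicates 1 and 2, 716 and 553 without wild-type IFNB1 replicates 1 and 2, 589 without Setd1aDel LPS replicate 2, and 710, 618 and 1876 without Setd1aDel IFNB1 replicates 1 to 3. The genes raised by 16 h of Dex had -0.0435 to 0.0674 at 6 h, and were called with -0.00216 without Setd1aDel LPS replicate 2 and -0.00784 without Setd1aDel Dex and LPS replicate 3. The IFNB1 genes had -0.0878 to -0.0742 at 6 h and were not called without wild-type LPS replicate 1 (-0.0742) or Setd1aDel LPS replicates 1 (-0.0748) and 3 (-0.0765). The correlation ran from -0.0193 to 0.00376. In the other counts of called genes leaving out a library gave a value within 1.5 times the main count. Without the genes of the chromosome stretches 4260, 5301 and 5725 genes were called for the deletion at 16 h, and 4607 and 5880 in the IFNB1 experiment.

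Of the calls of single named genes, a pseudocount of 0.1 ended those of Csf2 above, of Ifit1 and Rsad2 in the deletion effect with LPS and of Ifit3b, Ifit1, Mx1 and Ifit3 in the difference of Dex responses under LPS, both at 6 h, and that of Nr3c1 ended in vehicle with only the compared groups or without any of 5 libraries. Under scaling 34 list tests lost their call and 12 gained one, and 0 reversed. Depth limits are unknown because the tables hold TPM.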

Other observations

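The values here were looked at after the data were seen, and no explanation of them was tested. Further genes and lists, some named above, moved with LPS, Dex or genotype. In control marrow-derived macrophages LPS raised the stress genes Ier3 (4.58 ± 0.10) and Hspa1b (3.25 ± 0.13) and the cell cycle inhibitor Cdkn1a (3.59 ± 0.057), while Fos (-3.15 ± 0.11) fell. Of immediate early and dissociation stress genes, 9 of 13 rose and 4 fell (13 adjusted over the list alone, median 1.10, adjusted p = 0.00333). In wild-type RAW264.7 cells of the 16 h experiment Ier3 (4.56 ± 0.10), Atf3 (3.05 ± 0.12) and Junb (2.60 ± 0.10) rose, and 11 of 14 rose and 0 fell (11 adjusted over the list alone, median 1.33, adjusted p = 3.24e-09). Under LPS 6 h of Dex lowered Clec7a (-2.27 ± 0.19), the receptor for fungal glucan, Abca1 (-1.43 ± 0.066), Atf3 (-1.15 ± 0.15) and Tlr3 (-0.82 ± 0.095) in wild-type cells. Of genes for type I interferon induction and its receptor, 9 of 17 fell and 1 rose (10 adjusted over the list alone, median -0.14, adjusted p = 0.00236).

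In vehicle the libraries labelled Setd1bKO had lower C1qc (-1.48 ± 0.065), Folr2 (-1.91 ± 0.085), Axl (-1.35 ± 0.08) and Tlr7 (-1.90 ± 0.13), while Hmox1 (0.70 ± 0.064) was higher. In the 16 h RAW264.7 experiment the Setd1aDel vehicle libraries had higher p53 targets, with Fas (1.28 ± 0.17), Phlda3 (0.97 ± 0.16) and Cdkn1a (0.72 ± 0.036): 8 of 16 were higher and 2 were lower (11 adjusted over the list alone, median 0.16, adjusted p = 0.00125). With Dex and LPS at 6 h the glycolytic and hypoxia genes Ndrg1 (1.07 ± 0.19), Slc16a3 (0.45 ± 0.07) and Pfkfb3 (0.42 ± 0.059) were higher in Setd1aDel cells and Egr1 (-2.53 ± 0.12) and Axl (-1.20 ± 0.10) lower. Of glycolysis and hypoxia genes, 17 of 24 were higher and 1 was lower (18 adjusted over the list alone, median 0.24, adjusted p = 1.11e-07).

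The marrow-derived cells are labelled female, while the growth protocol speaks of male mice, and in a check on sex-linked genes 18 of 18 of these libraries did not match the label. The authors' and limma log2 changes had Pearson's r of 0.691 (IFNB1, wild type) to 0.982 (Dex under LPS, wild type, 6 h). In all 8 comparisons the commoner direction differed, as for control marrow-derived Dex (authors 1694 higher, 2404 lower, limma 4100 and 1389).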
